A study of Homo sapiens with 9 samples.

How the data were processed

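The 9 arrays measured total RNA from LNCaP cells, an established human prostate cancer line that responds to androgen, grown inside hollow fibers implanted in mice. Per the labels, the arrays fall into 3 stages, androgen dependent, androgen ablation and androgen independent, each with 1 array from each of the 3 mice 10R, 11L and 12R. The mice were castrated and fibers of the same mouse were taken at every stage, per the series' design text. Arrays are named below by stage and mouse, with AD for androgen dependent, AA for androgen ablation and AI for androgen independent, so that AD 10R is the androgen dependent array of mouse 10R. The times of harvest were not used here.

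The deposited values are an intensity per probe set on a linear scale. The submitters' processing notes name MAS5 and RMA, with no role or version for either. From the values, each array has a 2% trimmed mean of 500.1, the arrays' distributions are not identical and the values are not logarithms, which is the form MAS5 writes. Any other step before deposit is not given in the sources used here. The table holds 54675 probe sets, of which 62 are controls. In the platform annotation 41097 probe sets have 1 gene symbol, 1801 have several and 11777 are not named there. Of the 41091 probe sets with 1 symbol that are not controls, 41037 were matched by gene identifier to the RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. These probe sets stand for 19775 genes.

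Values were tested as log2(value + 16), so a fold change is on that scale and understates the change of dim genes. Probe sets with a mean below the 40th percentile of all probe sets (6.11 on the log2 scale) were left out, and each gene was represented by its probe set with the highest mean over the 9 arrays, which left 13439 genes. All 9 arrays entered a single limma fit with stage as the only term (lmFit and eBayes, no trend), with 6 residual and 2.3 prior degrees of freedom. Each p is two-sided and was adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed at an adjusted p under 0.05. A moderated F-test compared the 3 stages together. All adjusted p-values for genes come from limma. The unit of replication was the fibers taken from 1 mouse at 1 stage, and the number of arrays limits the precision of every value.

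The same 3 animals supplied every stage, per the labels, so the mice pair the samples. Deviations from the stage means of arrays of the same mouse had correlations across genes from -0.099 to 0.035 (median 0.008), against -0.06 to 0.104 (median -0.002) between mice. A fit with mouse as a block was run as an alternative.

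Gene lists, their members, the comparisons, the filter, the pseudocount, the rule for named genes and the alternatives listed below were fixed before the data were examined. Tests chosen after seeing the data were the share of calls kept without AD 10R, the luminal-marker test and the Fisher tests of returned genes, with and without mouse as a block. Of the 30 lists 1 is not reported here. The 29 others held androgen-induced and androgen-repressed genes, steroid synthesis and conversion enzymes, cholesterol synthesis, fatty acid synthesis, mitosis, DNA replication, cell cycle inhibitors and quiescence, neuroendocrine, hypoxia response, ER chaperone and protein folding, amino acid response, BCL2 family and apoptosis, WNT target, growth factor and receptor, interferon response, oxidative phosphorylation, cytosolic ribosomal protein, ribosome biogenesis, immediate early and heat shock genes, and epithelial to mesenchymal transition genes. The rest of the 29 held markers of prostate luminal and basal epithelium, fibroblasts, endothelium, leukocytes and macrophages, red blood cells, and adipocytes and muscle. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. Members past the threshold were counted with adjustment over all genes tested and adjusted over the list alone. The androgen-induced list shares 3 genes with the luminal markers, 2 with the ER chaperone list and 1 each with the cholesterol, fatty acid, hypoxia and transition lists.

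Named genes were, per comparison, the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose 3 arrays of 1 stage all lay above the 3 of the other. KLK3, KLK2, TMPRSS2 and FKBP5 were named in every comparison. Each list gave up to 4 members past the threshold with the largest change, or the 2 with the smallest p where none passed. The text prints part of that set. Genes named outside this rule are said to have been chosen after their values were seen.

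Alternatives were no filter, a filter at the 60th percentile, pseudocounts of 1 and 64, quantile normalization, centring each array on its median, an eBayes trend, mouse as a fixed or random block, only the 2 stages compared, the mean of a gene's probe sets, all probe sets, a 2-fold minimum, and leaving out each array or each mouse in turn. Where a stage was left with fewer arrays, its spread was taken from the pooled fit. The mean of a gene's probe sets was taken before the filter, so dim probe sets below the filter entered it.

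The test was tried on simulated data for ablation against dependence with 13439 genes, 5 draws and 250 changed genes per fold size in all. It recovered 12.4% of genes changed 1.5-fold, 60.4% at 2-fold, 92% at 4-fold and 97.6% at 8-fold, with a mean of 8.6 false calls a draw. A simulated shift of -0.5 in the mitosis list gave an adjusted p of 5.33e-16, and 0 of the 29 other lists were called by camera. All simulated noise was independent between genes, so this could not show how often camera calls correlated lists falsely. In the data the estimated correlation was 0.377 for mitosis and 0.835 for cytosolic ribosomal protein genes. It was 0.076 for DNA replication, 0.057 for fatty acid synthesis and -0.019 for cholesterol synthesis genes, the last below the preset value. The camera calls of these lists at ablation ended with an estimated correlation too. Correlation between genes therefore does not by itself account for the calls that ended. Comparisons that share arrays were set against 100 simulated draws with no effect. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.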

Results

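Expression was measured in LNCaP cells recovered from fibers at 3 stages, with 3 arrays per stage and 9 arrays in all. The median signal was 83.3 on the array AD 10R and lay between 99.6 and 109.8 on the others. On AD 10R the β-actin control signal at the 3′ end was 2.999 times that at the 5′ end, against 0.944 to 1.146 on the other arrays, and the 18S ribosomal RNA control read 287.8 against 2270 to 3785.4. The GAPDH 3′ to 5′ ratio lay between 0.92 and 1.183 on all 9 arrays. Arrays of the same stage had Pearson correlations across genes of 0.957 to 0.975. The stages separated on the first principal component, which held 38.4% of the variance, in the order dependent, ablation, independent. By limma's F-test 2474 of the 13439 genes differed among the stages, or 1698 with mouse as a block. The F-test count was 1594 without AD 11L, 1570 without AI 10R, 1622 without AI 11L and 1524 without AI 12R.

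**Figure D1:**
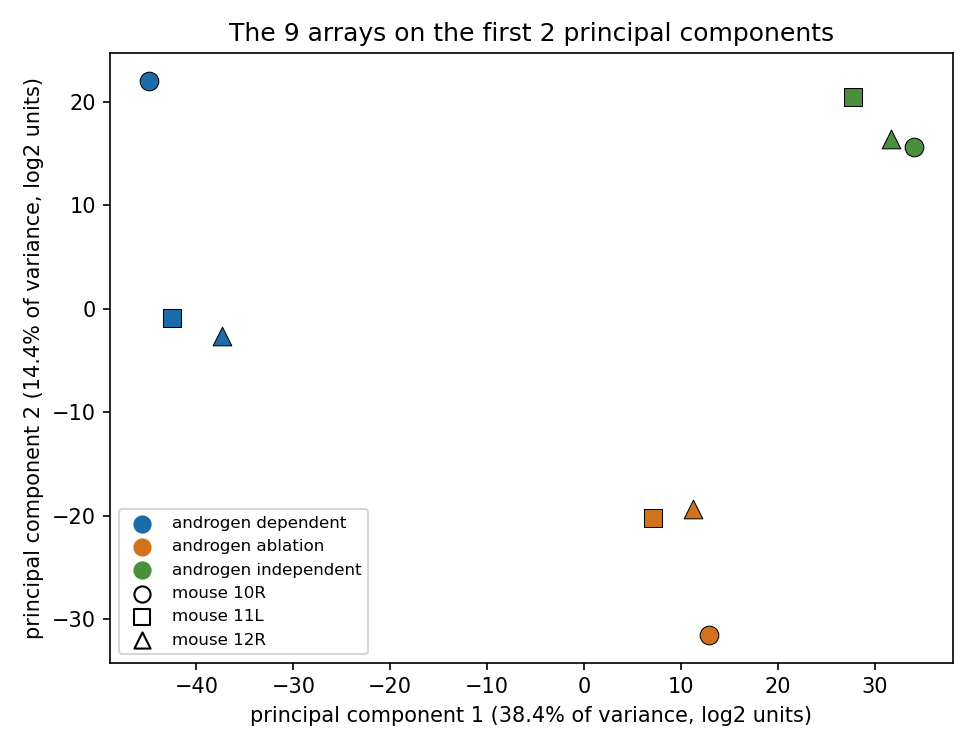
The 9 arrays on the first principal component (horizontal axis, 38.4% of variance) and the second (vertical axis, 14.4%), in log2 units, with colour for stage and marker shape for mouse. The androgen dependent arrays lie at the left and the androgen independent arrays at the right, and AD 10R lies apart from the other 2 dependent arrays on the vertical axis.

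The comparison of ablation with dependence asked what changed in the cells after castration. Of the measured list members 32 of 35 mitosis, 21 of 33 DNA replication and 19 of 35 androgen-induced genes fell, and 5 of 8 androgen-repressed genes rose. None of these 4 lists passed camera with an estimated correlation, where the adjusted p ran from 0.0639 to 0.109. FKBP5, a steroid receptor co-chaperone induced by androgen, went from a signal of 20350 ± 2002 to 2376 ± 292 (SD, n = 3 arrays each), a log2 fold change of -3.09 (SE 0.134, adjusted p = 0.000106). OPRK1, the kappa opioid receptor, rose from 95.97 ± 9.474 to 2651 ± 826.1, a log2 fold change of 4.53 (SE 0.213, adjusted p = 0.000107). In all, 1438 genes passed, 661 higher and 777 lower, and 523 of them changed at least 2-fold.

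Of the 35 measured androgen-induced genes, 0 rose and 19 fell, or 25 adjusted over the list alone, with a median log2 fold change of -0.74. Its camera adjusted p was 1.97e-13, and the adjusted p = 0.109 with an estimated correlation, in a range of 1.19e-16 to 0.182 over the alternatives. Beside FKBP5, the prostaglandin-degrading enzyme HPGD fell by 3.2 on the log2 scale, the metalloreductase STEAP4 fell by 3.32 and the condensin II subunit NCAPD3, which acts in chromosome condensation, fell by 2.86. The mean of the STEAP4 probe sets, those below the filter included, gave -1.93. KLK3, which encodes prostate-specific antigen, had 36920 ± 7979 at dependence and 22280 ± 5899 at ablation, a log2 fold change of -0.74 (SE 0.231) that did not pass (adjusted p = 0.0818). Without AD 10R its adjusted p was 0.0401 and with mouse as a block 0.0419, in a range of 0.0184 to 0.373 over the alternatives. TMPRSS2, a membrane serine protease, had a log2 fold change of -0.48 (adjusted p = 0.0845), or 0.0386 without AD 10R, with a range of 0.0211 to 0.44. The kallikrein KLK2 had a log2 fold change of -1.38 (SE 0.338, adjusted p = 0.0384). That call ended without AD 10R, AD 11L, AA 10R, AA 11L or any 1 of the AI arrays (adjusted p from 0.0531 to 0.111) and with mouse as a block (0.0759), in a range of 0.00493 to 0.255.

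Of the 8 measured androgen-repressed genes 5 rose and 0 fell, the same counts as adjusted over the list alone, with a median of 1.21. The camera adjusted p was 1.45e-06, and the adjusted p = 0.0897 with an estimated correlation, in a range of 1.1e-08 to 0.124. OPRK1 belonged to this list, as did the synaptic protein gene SLITRK3, with a log2 fold change of 2.16 (SE 0.185), the CaMKII inhibitor CAMK2N1 with 1.96 (SE 0.256) and butyrylcholinesterase BCHE with 1.66 (SE 0.197).

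Mitosis genes gave the largest list shift of the comparison. Of 35 measured members 32 fell and 0 rose, or 35 adjusted over the list alone, with a median of -1.68. The camera adjusted p was 4.24e-26, and the adjusted p = 0.0897 with an estimated correlation, in a range of 2.02e-33 to 0.124. MYBL2, a transcription factor of cell cycle genes, fell by 3.17 on the log2 scale (SE 0.332), the spindle checkpoint kinase TTK fell by 2.9 and the spindle protein gene DLGAP5 fell by 2.78. Of 33 DNA replication genes 21 fell and 0 rose, or 26 adjusted over the list alone, with a median of -0.91. Their camera adjusted p was 1.9e-15, and the adjusted p = 0.0639 with an estimated correlation, in a range of 1.1e-18 to 0.112. The replication and methylation maintenance gene UHRF1 fell by 3.34 (SE 0.315) and CDC45, part of the replicative helicase, fell by 2.46 (SE 0.273). RRM2, a subunit of ribonucleotide reductase, fell by 3.49 (SE 0.666, adjusted p = 0.0164), a call that ended without AD 11L (0.0516) or AA 10R (0.0584), in a range of 0.00103 to 0.135. Of 18 cell cycle inhibitors and quiescence genes 1 rose and 0 fell under both adjustments.

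Of 20 cholesterol synthesis genes 9 fell and 0 rose, 5 with mouse as a block, while adjusted over the list alone 11 fell and 1 rose, with a median of -0.39. Of 15 fatty acid synthesis genes 5 fell and 0 rose, or 7 adjusted over the list alone, with a median of -0.58. Camera gave adjusted p-values of 0.000309 and 8.45e-05 for these lists, and the adjusted p = 0.0707 for cholesterol and 0.0897 for fatty acid genes with an estimated correlation. Over the alternatives the ranges were 4.66e-05 to 0.124 and 1.22e-05 to 0.124. The cholesterol transporter gene STARD4 fell by 1.83 (SE 0.256), INSIG1, which restrains sterol synthesis, fell by 1.04 and the elongase ELOVL7 fell by 1.78. Fatty acid synthase, FASN, fell by 1.86 (SE 0.254, adjusted p = 0.00425). The mean of its probe sets, those below the filter included, gave -0.71 (adjusted p = 0.193), in a range of 9.12e-05 to 0.193 over the alternatives. Of 20 ribosome biogenesis genes 4 fell and 0 rose, 2 with mouse as a block and 7 adjusted over the list alone. Their median was -0.3 with a camera adjusted p of 0.000397, and the adjusted p = 0.31 with an estimated correlation, in a range of 4.66e-05 to 0.31. The spermidine synthase gene SRM fell by 0.91.

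Genes outside these lists changed as well. The secreted phospholipase PLA2G2A rose by 3.8 on the log2 scale (SE 0.217), from 465.4 ± 108.8 to 6750 ± 1764. The relaxin genes RLN1 and RLN2, near-identical neighbours whose probe sets may not tell them apart, had log2 fold changes of 3.12 and 2.74. The cell surface genes LRRN1 and AMIGO2 rose by 3.27 and 3.45, the neuronal serine protease inhibitor SERPINI1 by 3.07 and the reelin adaptor DAB1 by 3.36. Pepsinogen C, PGC, fell by 4.42 (SE 0.407), from 1818 ± 253.5 to 77.87 ± 47.02. The membrane protein gene TM4SF1 fell by 3.9, the disulfide isomerase AGR2 fell by 3.69 and the calcium-binding S100P fell by 3.46. The mean of the AGR2 probe sets, those below the filter included, gave -2.42. HBE1, embryonic globin, had the largest log2 fold change of all, 5.14, but a wide error (SE 1.248, adjusted p = 0.037). That call ended without any 1 of the AD or AA arrays or AI 10R (0.0575 to 0.113). The mean of the HBE1 probe sets, those below the filter included, gave 2.39 (0.0857), in a range of 0.00442 to 0.187 over the alternatives.

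Lists of energy and ribosomal genes shifted slightly with 0 members past the threshold in limma. The median of 36 oxidative phosphorylation genes was -0.15 (camera adjusted p = 0.00729) and that of 35 cytosolic ribosomal protein genes -0.11 (0.0343). With an estimated correlation the adjusted p = 0.729 for both, and under quantile normalization the p-values were 0.583 and 0.686. The first call ended without AA 10R (0.0972) and the second without AD 11L (0.0957), AD 12R (0.614) or AA 10R (0.241). Over the alternatives the ranges were 0.00185 to 0.729 and 3.6e-05 to 0.797.

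The other lists reported here did not pass in camera, though some did under alternatives. Higher and lower members numbered 1 and 2 of 16 steroid enzymes, 1 and 0 of 9 neuroendocrine genes, 0 and 3 of 30 hypoxia genes, and 0 and 3 of 25 ER chaperone genes. They numbered 0 and 1 of 24 amino acid response genes, 2 and 2 of 23 BCL2 family genes, 2 and 2 of 23 growth factor and receptor genes, 2 and 0 of 21 interferon genes, 4 and 2 of 18 immediate early genes, 2 and 0 of 11 heat shock genes, and 1 and 1 of 7 transition genes. Of 10 WNT target genes 0 passed, and their median of 0.03 and mean of -0.15 differed in sign. Adjusted over the list alone, higher and lower members numbered 1 and 3 of the steroid enzymes, 0 and 4 of the ER chaperone genes, 0 and 0 of the amino acid response genes, 3 and 2 of the BCL2 family, 2 and 4 of the growth factor genes, 6 and 2 of the immediate early genes and 3 and 1 of the transition genes, with the other counts of these lists the same. With mouse as a block limma gave 0 interferon genes, 0 higher steroid enzymes, 1 heat shock gene, 1 higher and 1 lower BCL2 family gene and 1 lower immediate early gene, where 3578 of all genes had an unadjusted p under 0.05 in the fit without it. With all arrays the hypoxia list passed camera with no filter (adjusted p = 0.0352), the 60th percentile filter (0.0485), median centring (0.0384) and an eBayes trend (0.0264). It also passed without AD 10R (0.0325), AA 11L (0.0128) or AI 10R (0.0461), in a range of 0.0128 to 0.729, and the immediate early list with no filter (0.0421), median centring (0.0384) or without AA 12R (0.0107), in a range of 0.0107 to 0.729. The ER chaperone list passed with no filter (0.0421), an eBayes trend (0.045) or without AA 11L (0.0414), in a range of 0.0401 to 0.748. Among named members, the hypoxia gene LOX, a collagen cross-linking enzyme, fell by 2.04 (SE 0.161), the transcription factor JUN rose by 1.04, the aromatic amino acid decarboxylase DDC rose by 2.09, the steroid 5-alpha-reductase SRD5A1 fell by 0.63 and the insulin receptor substrate IRS2 fell by 0.98.

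Markers of other cell types did not move as one. Of 14 luminal markers 1 rose and 3 fell, or 2 and 5 adjusted over the list alone. The prostatic acid phosphatase ACP3 rose by 1.8 (SE 0.224) while the keratin KRT18 fell by 0.92. The luminal median was -0.29 (camera adjusted p = 0.206), and without AD 10R, the array with the high β-actin 3′ to 5′ ratio, it was -0.67 (adjusted p = 0.00305), in a range of 0.000957 to 0.729. Higher and lower markers numbered 0 and 0 of 4 for basal cells, 1 and 0 of 7 for fibroblasts, 0 and 0 of 5 for endothelium, 0 and 0 of 5 for leukocytes and macrophages, 1 and 0 of 3 for red blood cells, and 0 and 0 of 4 for adipocytes and muscle, all by limma. At an unadjusted p under 0.05 limma gave 3578 of all genes. Adjusted over the list alone 1 basal marker rose, 1 fibroblast marker rose and 1 fell, and the counts of the other types did not change. With mouse as a block 1 fibroblast marker rose and 1 fell.

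All 3 arrays of 1 stage lay above all 3 of the other for 4248 genes, 31.6%, where chance gives 10%. With mouse as a block 913 genes passed, 423 higher and 490 lower, 866 of them shared with the fit without it. Centring each array on its median gave 847 genes, 290 higher and 557 lower, so that 34.2% were higher against 46%. The count was 740 without AD 11L, 848 without AD 12R, 643 without AA 10R, 779 without AA 11L and 713 without AA 12R. Without AD 10R it was 1464, and the balance turned round, with 793 higher and 671 lower. It did so too with the mean of a gene's probe sets, 559 and 526, and with all probe sets, 1080 and 853.

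**Figure D2:**
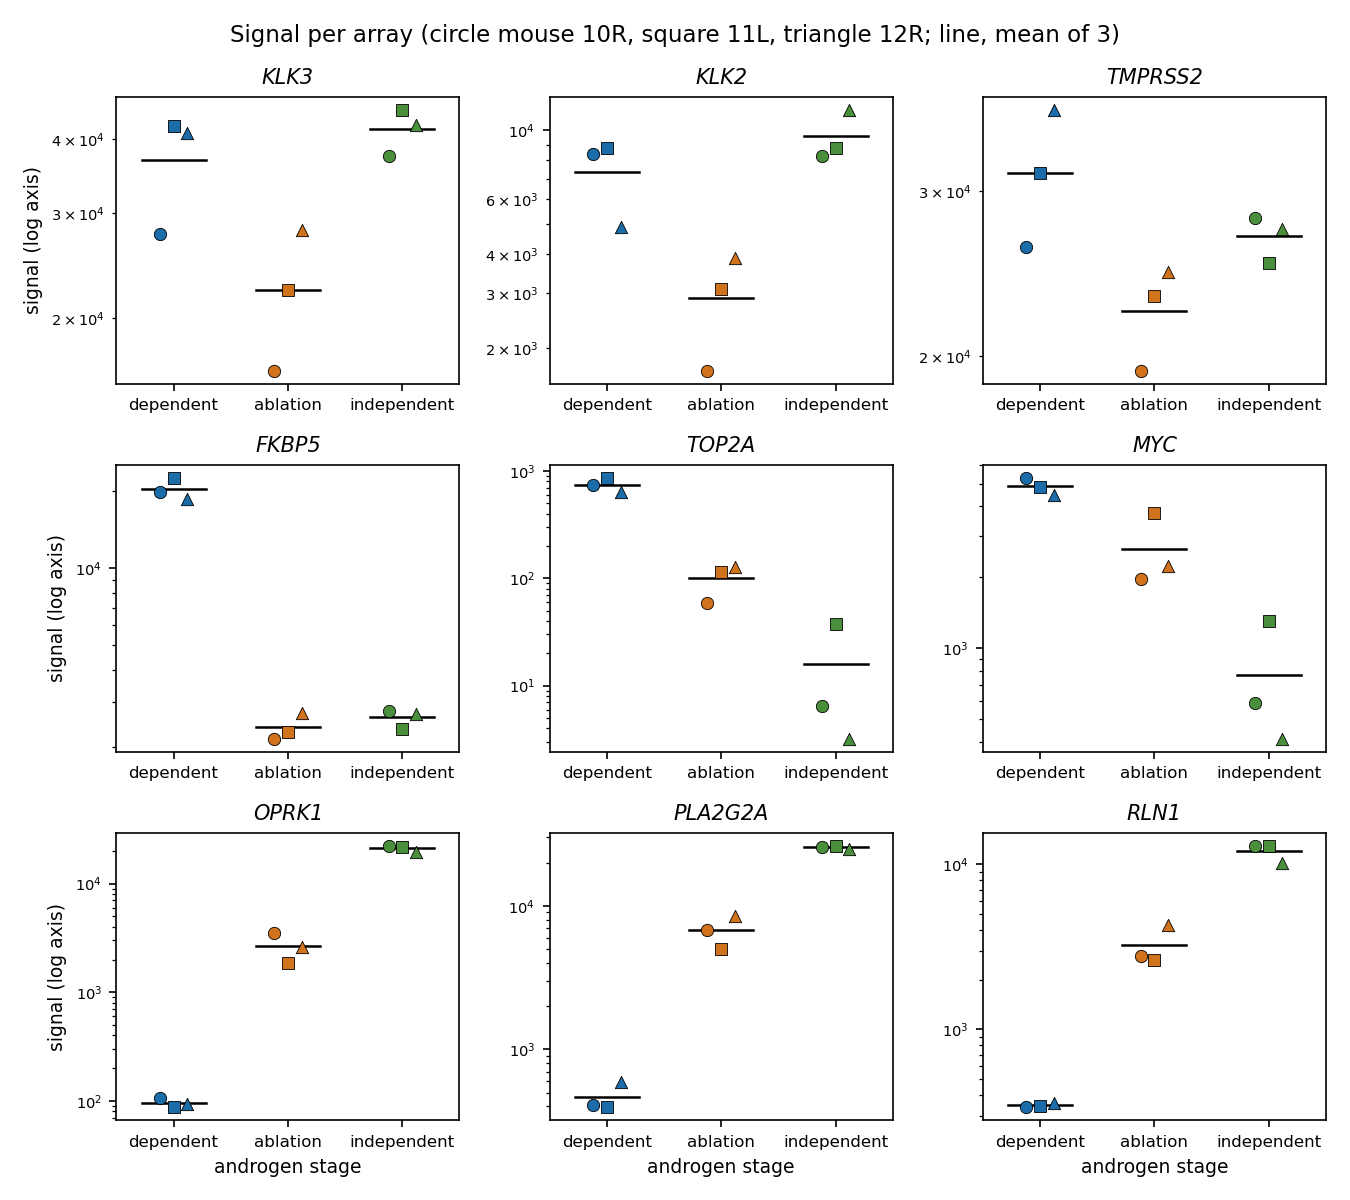
Signal of 9 genes on each array (vertical log axes, deposited signal) by stage, with marker shape for mouse and a line at the mean of 3 arrays. FKBP5 stays low at independence (2600) while KLK2 and KLK3 lie at 9565 and 41500 there, TOP2A and MYC fall to 15.77 and 769.5, and OPRK1, PLA2G2A and RLN1 rise to 21110, 25550 and 11950.

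The comparison of independence with dependence asked how the late cells differed from those before castration. Most mitosis and DNA replication genes were lower than at dependence, FKBP5 stayed low, and KLK3 and KLK2 did not pass the threshold. OPRK1 rose by 7.56 on the log2 scale (SE 0.213, adjusted p = 3.19e-06), to a signal of 21110 ± 1564. PLA2G2A reached 25550 ± 594.4, a log2 fold change of 5.75 (SE 0.217). FKBP5 had a log2 fold change of -2.96 (SE 0.134, adjusted p = 3.03e-05). In all, 2644 genes passed, 1277 higher and 1367 lower, and 873 changed at least 2-fold.

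Of the 35 mitosis genes 34 fell and 0 rose, or 35 adjusted over the list alone, with a median of -2.42. The camera adjusted p was 2.52e-26, and the adjusted p = 0.214 with an estimated correlation, in a range of 3.85e-35 to 0.214. DNA topoisomerase TOP2A fell by 4.74 (SE 0.398), from 747.7 ± 111.1 to 15.77 ± 19.06, the spindle protein gene NUSAP1 fell by 3.63 and survivin, BIRC5, fell by 3.62. The means of the probe sets gave -2.83 for TOP2A and -2.36 for BIRC5. Of the 33 DNA replication genes 25 fell and 0 rose, or 27 adjusted over the list alone, with a median of -1.14. Their camera adjusted p was 3.95e-14, and the adjusted p = 0.0802 with an estimated correlation, in a range of 4.3e-18 to 0.13. RRM2 fell by 5.44 and CDC45 fell by 4.04. MYC, a transcription factor of growth and ribosome genes, had 4871 ± 409.2 at dependence and 769.5 ± 474.3 at independence, a log2 fold change of -2.8 (SE 0.401, adjusted p = 0.00268). Of 20 ribosome biogenesis genes 6 fell and 1 rose, or 12 and 1 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.00175). The adjusted p = 0.53 with an estimated correlation, in a range of 0.000278 to 0.53. The polyamine enzyme genes ODC1 and SRM fell by 1.48 and fell by 1.02. Of 35 cytosolic ribosomal protein genes 6 fell and 0 rose, or 5 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.000205), and the adjusted p = 0.739 with an estimated correlation, in a range of 1.54e-07 to 0.739. Without mouse 12R their median was -0.081 and the call ended (camera adjusted p = 0.244). RPL14, of the large ribosomal subunit, fell by 0.78.

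Of the 35 androgen-induced genes 15 fell and 2 rose, 1 rising with mouse as a block, or 17 and 4 adjusted over the list alone, with a median of -0.53. The camera adjusted p was 0.000205, and the adjusted p = 0.6 with an estimated correlation, in a range of 1.11e-05 to 0.623. STEAP4 fell by 3.34 and NCAPD3 fell by 2.86. KLK3, KLK2 and TMPRSS2 had log2 fold changes of 0.19, 0.41 and -0.21 (adjusted p = 0.615, 0.444 and 0.373). Of the 8 androgen-repressed genes 5 rose and 1 fell under both adjustments, with a median of 1.05 (camera adjusted p = 0.0167), and the adjusted p = 0.53 with an estimated correlation, in a range of 0.000309 to 0.623. The member that fell was the chemokine receptor ACKR3, with a log2 fold change of -1.66 (SE 0.182). Of 20 cholesterol synthesis genes 6 fell and 0 rose, or 7 adjusted over the list alone, with a median of -0.19 and a camera adjusted p of 0.0217. With an estimated correlation the adjusted p = 0.237, and the call ended without AD 11L (0.0601), AD 12R (0.0562) or AI 11L (0.0505), in a range of 0.00155 to 0.373. FDPS, of the mevalonate pathway, fell by 0.71. Among the 15 fatty acid synthesis genes 3 fell and 1 rose (camera adjusted p = 0.157, or 0.0261 by fry and 0.0494 with no filter, in a range of 0.0261 to 0.632), where ELOVL7 fell by 1.81 and the lipid transcription factor SREBF1 rose by 1.1.

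Of 21 interferon response genes 6 rose and 0 fell under both adjustments, 2 with mouse as a block, with a median of 0.4 (camera adjusted p = 0.0168). With an estimated correlation the adjusted p = 0.53, and without AD 10R it was 0.0689, in a range of 0.00309 to 0.623. IFI35 rose by 1.3 (SE 0.172). Leukocyte and macrophage markers had a median of 0.73 with 4 of 5 positive and 0 past the threshold in limma (camera adjusted p = 0.379, and 0.0928 by fry, in a range of 0.0928 to 0.863). Of 4 basal markers 2 rose and 0 fell under both adjustments (camera adjusted p = 0.369, and 0.0276 by fry, in a range of 0.0276 to 0.795). The ligand CD274, also named PD-L1, rose from 71.07 ± 16.52 to 2214 ± 551.4, a log2 fold change of 4.67 (SE 0.287, adjusted p = 7.5e-05). The relaxin genes RLN1 and RLN2 had log2 fold changes of 5.03 and 3.94. In the gene order of GRCh38.p14 the measured genes run RLN2, RLN1, PLGRKT, CD274, and PLGRKT, chosen after its value was seen, had 1.51 (adjusted p = 0.00159). The calcium-binding gene CPNE4 rose by 4.87, the endocytic adaptor STON1 by 4.77 and ACP3 by 3.77 (SE 0.224). The glucocorticoid receptor NR3C1 rose by 2.76 (SE 0.378), from a signal of 37.73 ± 18.42 to 351.7 ± 143.2. The synaptic vesicle gene SYT1 rose by 3.48 and the basal keratin KRT14 by 2.57. Of 7 transition genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone, where the transcription factor ZEB2 rose by 2.03 and SNAI2 fell by 2.73. TM4SF1 fell by 5.47, the neuropeptide galanin, GAL, fell by 4.08, LOX fell by 3.6 and the growth factor EGF fell by 1.97. The mean of the GAL probe sets, those below the filter included, gave -2.08. The apoptosis gene BID fell by 1.23 and the folate enzyme MTHFD2 fell by 1.8.

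Of 23 BCL2 family genes 5 fell and 1 rose, of 30 hypoxia genes 6 fell and 0 rose, and of 36 oxidative phosphorylation genes 5 fell and 0 rose, lists that did not pass in camera. The BCL2 family list did by fry (0.0297), in a range of 0.0297 to 0.725. Adjusted over the list alone the lower members numbered 5, 6 and 3, and with mouse as a block 4, 3 and 3, with 0 higher in limma. The hypoxia list had a camera adjusted p of 0.0572, and passed with no filter (0.0283), with an eBayes trend (0.0265), by fry (0.0261), and without AD 10R (0.0386), AA 11L (0.0475), AI 11L (0.0348) or AI 12R (0.0213), in a range of 0.0213 to 0.725. The oxidative phosphorylation list passed without AD 10R (0.0422) or AI 11L (0.0298), in a range of 0.0298 to 0.808.

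The stages were fully separate for 5110 genes, 38%, where chance gives 10%. With median centring 1757 genes passed, 669 higher and 1088 lower, so that 38.1% were higher against 48.3%. The count was 1663 without AI 10R and 1666 without AI 12R. Without AD 10R it was 2704, and the balance turned round, with 1422 higher and 1282 lower, as it did with the mean of a gene's probe sets, 1084 and 969, and with all probe sets, 2155 and 1868.

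The comparison of independence with ablation asked what changed after castration had taken effect. Fewer genes passed, 380 in all with 231 higher and 149 lower, and 140 changed at least 2-fold. OPRK1 rose a further 3.03 on the log2 scale (SE 0.213, adjusted p = 0.00126) and ACP3 rose by 1.97 (SE 0.224, adjusted p = 0.00808). The long noncoding RNA LINC00844 rose from 233.7 ± 55.73 to 1840 ± 117.4, a log2 fold change of 2.92 (SE 0.163, adjusted p = 0.000434), and the prostate noncoding RNA PCGEM1 rose from 385.9 ± 79.82 to 2191 ± 170.3, one of 2.47 (SE 0.278). The defensin gene DEFB132 rose by 2.57 (SE 0.127) and CPNE4 rose by 2.69. ACKR3 fell by 2.42 (SE 0.182), from 3396 ± 543.1 to 622.8 ± 112.3. The means of the probe sets gave -1.19 for ACKR3 and 1.58 for PCGEM1. The growth factor receptor adaptor GRB10 fell by 1.92 (SE 0.137), the secreted protein gene TAFA2 fell by 2.33 and FRY fell by 2.3. LOX fell by 1.56 (SE 0.161, adjusted p = 0.00553), though the mean of its probe sets gave an adjusted p of 0.0578, in a range of 0.000165 to 0.16.

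Of the 35 androgen-induced genes 5 rose and 0 fell, 1 with mouse as a block, while adjusted over the list alone 9 rose and 1 fell, with a median of 0.34. The camera adjusted p was 0.000534, and the adjusted p = 0.581 with an estimated correlation and 0.0896 with fry, in a range of 1.24e-05 to 0.714. The median was 0.13 without AA 10R. KLK2 went from 2889 ± 1106 to 9565 ± 1828, a log2 fold change of 1.79 (SE 0.338, adjusted p = 0.0389). That call ended without AD 11L, AA 10R, AA 11L or any 1 of the AI arrays (0.0562 to 0.116) and with mouse as a block (0.086), in a range of 0.00235 to 0.327. KLK3 had a log2 fold change of 0.93 (SE 0.231) that did not pass (adjusted p = 0.0768) and did without AD 10R (0.0492), in a range of 0.0117 to 0.427. FKBP5 had 0.13 (adjusted p = 0.644) and TMPRSS2 had 0.27 (adjusted p = 0.391).

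Mitosis genes had a median of -0.66 with 1 of 35 past the threshold as lower, or 5 adjusted over the list alone, and a camera adjusted p of 7.58e-08. The adjusted p = 0.581 with an estimated correlation, in a range of 4.38e-15 to 0.714, and 0 members passed in limma with mouse as a block, where 2542 of all genes had an unadjusted p under 0.05 in the fit without it. DNA replication genes had a median of -0.24 with 2 of 33 lower and 0 higher, 1 lower with mouse as a block, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0225). The adjusted p = 0.581 with an estimated correlation, and the call ended without AA 11L (0.0565) or AI 12R (0.114), in a range of 0.0021 to 0.714. Fatty acid synthesis genes had a median of 0.38 with 1 of 15 higher and 0 lower under both adjustments (camera adjusted p = 0.0234). The adjusted p = 0.581 with an estimated correlation, and the call ended without AA 10R (0.0891), AA 11L (0.0503), AI 11L (0.0521) or AI 12R (0.101), in a range of 0.00386 to 0.714. With the mean of a gene's probe sets the median of the fatty acid list was 0.144 (camera adjusted p = 0.197). Cytosolic ribosomal protein genes had a median of -0.13 with 0 of 35 past the threshold (camera adjusted p = 0.016). The adjusted p = 0.88 with an estimated correlation, and the call ended without AA 11L (0.0754), AA 12R (0.0529) or AI 12R (0.307), in a range of 0.000124 to 0.88.

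This comparison lost a larger share of its calls than the others without single AA or AI arrays and with mouse as a fixed block. With that block 62 genes passed, 43 higher and 19 lower, 61 of them shared with the fit without it. The fixed block left 4 residual degrees of freedom against 6, so the lower count does not by itself show differences between mice. With mouse as a random block 286 genes passed. The count was 588 without AD 10R, 204 without AD 11L, 200 without AD 12R, 50 without AA 10R, 37 without AA 11L, 151 without AA 12R, 54 without AI 10R, 53 without AI 11L and 75 without AI 12R. Stages were fully separate for 3971 genes, 29.5%, where chance gives 10%.

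**Figure D3:**
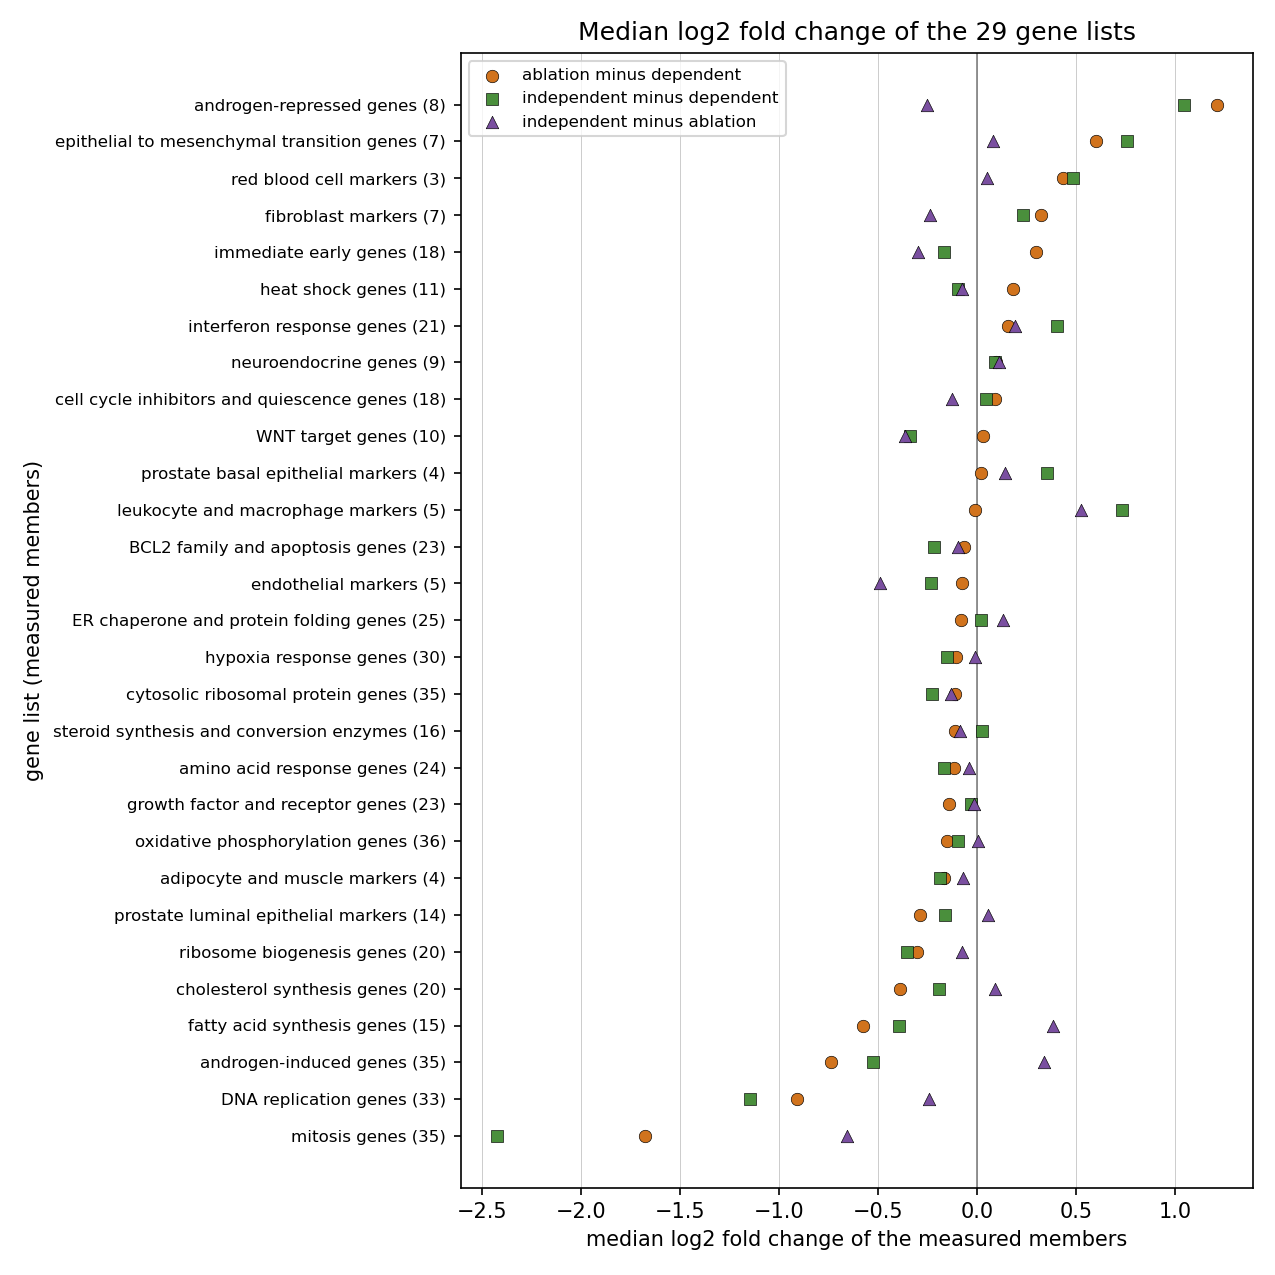
Median log2 fold change (horizontal axis) of the measured members of 29 gene lists (vertical axis, number measured in brackets) in the 3 comparisons, as circles, squares and triangles. Mitosis genes lie lowest in the comparisons with the dependent stage, at -1.68 and -2.42, and androgen-repressed genes highest, at 1.21 and 1.05.

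The order of the stages raised the question of which changes at ablation persisted. Of the 1438 genes changed at ablation 1029, 71.6%, were changed in the same direction at independence against dependence, among them FKBP5, PGC, UHRF1 and OPRK1. Returned genes, which passed in the opposite direction between ablation and independence, numbered 58, 4%, with 7 of them in both groups. Of the 58, 40 were genes lowered at ablation and 18 raised. More genes, 69, passed between ablation and independence in the same direction as at ablation, 19 of them lowered and 50 raised. Of the 19 androgen-induced genes lowered at ablation 14 were still lower at independence and 4 returned, KLK2, GNMT, PMEPA1 and TRPM8. GNMT counted in both, since it still lay below dependence, with a log2 fold change of -1.21 (adjusted p = 0.00198). GNMT, a methyltransferase, rose by 1.15 between ablation and independence (adjusted p = 0.017), the transforming growth factor regulator PMEPA1 by 1.59 (0.0461) and the cold-sensing channel TRPM8 by 1.3 (0.0289). The GNMT call ended without AA 10R, AA 11L or any 1 of the AI arrays (0.0555 to 0.07), those of PMEPA1 (0.069 to 0.132) and TRPM8 (0.0503 to 0.0994) also without AD 11L or AD 12R, and with mouse as a block GNMT had 0.0645 and PMEPA1 0.0922. Over the alternatives the ranges were 0.000705 to 0.284 for GNMT, 0.00398 to 0.33 for PMEPA1 and 0.00129 to 0.328 for TRPM8.

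Both comparisons with the dependent stage used the same 3 arrays. Across genes, which are not independent replicates, their log2 fold changes had a correlation of 0.759, against 0.5 in simulated draws with no effect. The covariance was 0.255 against 0.035, a difference of 0.22, and 75.4% of genes had the same sign against 66.7%. Lists drawn independently would share 141.8 genes in the same direction, and 20.7 for the returned genes. Simulated draws with no effect gave 0 for both. They called a mean of 0.01 genes at ablation, so that 0 is no measure for the counts of 1029 and 58. In draws with independence equal to ablation, means of 2677.33 genes were called at ablation and 1992.65 persisted. With 3 dependent arrays the controls cannot be parted into groups of at least 2 each. Part of the excess of 1029 over 141.8 may therefore come from the shared dependent arrays. Part of that of 58 over 20.7 may come from the shared ablation arrays. The no-effect draws shared arrays too, and their highest covariance was 0.038. The excess of the correlation and covariance is thus beyond sharing for noise independent between genes. Noise that many genes share was not simulated and may contribute. The count of 1029 was 577 without AD 11L, 662 without AD 12R, 544 without AA 10R, 620 without AA 11L and 560 without AA 12R. The count of 58 was 13 with mouse as a block, 24 without AD 11L, AD 12R or AA 12R, 8 without AA 10R, 11 without AA 11L or AI 10R, and 12 without AI 11L or AI 12R.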

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

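The test of the share of calls kept without AD 10R was chosen only after its result could be seen, and the splits of the arrays were chosen before. The β-actin control on AD 10R, read outside the gene comparisons, had a 3′ to 5′ ratio of 2.999 where the other 8 arrays had at most 1.146. Without that array 79.6% of the calls against the dependent stage were kept in the same direction.

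Probe sets without a single gene symbol, which no gene comparison used, also passed the threshold. They numbered 296 between ablation and dependence, 622 between independence and dependence and 56 between independence and ablation, of 6486 tested.

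Each pairwise count was set against the 10 splits of its 6 arrays, which are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real splits gave 1438, 2644 and 380 genes, and the highest other split gave 0 by limma in each, with up to 919, 901 and 509 genes at an unadjusted p under 0.05. Since the mice pair the samples, the real split was also compared with the 3 others that part all 3 mice, each of which gave 0 genes by limma. For the F-test, 1 of 100 drawn splits of the 9 arrays, the real one, gave as many as 2474 genes, and the highest other gave 742. Among the 36 splits that part the arrays of every mouse 1 did, with 806 as the highest other. Chance is argued against for that count, though the 36 splits allow no share smaller than 1 of 36.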

How the results depend on the processing

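The alternatives here, leaving out each array included, had been listed beforehand, except that the Fisher test of returned genes with the replicate block (odds ratio 5.16 against 5.32, p = 0.209) was chosen after seeing the data, as was the share of calls kept without AD 10R. Over all-array alternatives the named genes kept their call in 2932 of 3361 cases, with 391 no longer past the threshold, 35 newly past it and 3 reversed. Lists kept theirs in 1080 of 1164, with 64 no longer past, 20 newly past and 0 reversed. A change of sign counted as reversed only where the main call had passed, and otherwise as a kept call. With arrays left out the named genes kept their call in 2427 of 3444 cases, with 1007 no longer past and 0 reversed, and lists in 1028 of 1080. With the mean of a gene's probe sets BCL2L1 at ablation had 0.312. HSD17B4 at independence had -0.02 against dependence and -0.12 against ablation, where probe sets below the filter entered the mean. The cause was not tested. Counts are given in the order ablation against dependence, independence against dependence, independence against ablation, F-test, persisting, returned, where they moved over 1.5 times. No filter, which tests more genes, gave 752, 88 for the third, 1538, 558 and 14. A filter at the 60th percentile, with fewer genes tested, gave 711 for independence against ablation and 125 returned. Median centring gave 847, 1757, 116, 1504, 618 and 17. Centring raised AD 10R, whose median signal of 83.3 was the lowest. The median log2 fold change of all genes went from -0.002 to -0.093 at ablation and from -0.006 to -0.087 at independence, both against dependence. Whether that array caused the lost calls was not tested. An eBayes trend gave 839 for independence against ablation and 145 returned. The mean of probe sets gave 198 for independence against ablation, and the cause was not tested. The replicate block, with mouse as the pairing, gave 913, 62 for independence against ablation and 13 returned. Part of the changes it made to calls of genes and to list counts is given with them. Other list counts that it lowered fell by differing amounts. BCL2 family genes lower against ablation went from 4 to 0 and immediate early genes higher at independence from 5 to 3. DNA replication genes lower at ablation went from 21 to 16. Only the 2 stages compared, with fewer arrays, gave 751 and 225 for independence against ablation. All probe sets, with more features tested, gave 4023 for independence against dependence, and a 2-fold minimum gave 523, 873, 140 and 975 by the F-test. List shifts lost their calls with an estimated correlation, alone or with the replicate block, at unmoved medians: androgen-induced -0.738, androgen-repressed 1.21, mitosis -1.675 and DNA replication -0.907 at ablation, then -0.527, 1.046, -2.425 and -1.144 at independence, then 0.34, -0.656 and -0.241 for androgen-induced, mitosis and DNA replication genes against ablation. With fry the last 3 had the same medians and an adjusted p of 0.0896. DNA replication genes there had -0.232 with the 60th percentile filter (0.0721) and -0.241 with only the 2 stages (0.0519), in a range of 0.0021 to 0.714. Leaving out 1 array or 1 mouse, with fewer arrays tested, gave 99 to 1464, 487 to 2704, 0 to 588, 227 to 2616, 82 to 1100 and 0 to 78 genes. Without mouse 10R or 11L limma gave 0 genes for independence against ablation, with 2200 and 1475 at an unadjusted p under 0.05. In these fits the medians ran from -0.865 to -0.624, 1.087 to 1.305, -1.822 to -1.569 and -0.94 to -0.839 at ablation, -0.623 to -0.401, 0.888 to 1.267, -2.564 to -2.191 and -1.144 to -1.011 at independence, and 0.129 to 0.45, -0.373 to 0.173, -0.892 to -0.448 and -0.279 to -0.161 against ablation, for the androgen-induced, androgen-repressed, mitosis and DNA replication lists. The androgen-repressed call at independence against dependence ended without mouse 10R (0.0566), in a range of 0.000309 to 0.623. List shifts with mouse as a random block or over all probe sets were not run, and an F-test over only 2 stages does not apply. Signal near background limits dim genes, whose fold changes the pseudocount shrinks.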

Other observations

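The luminal-marker test and the Fisher tests, with and without mouse as a block, were chosen only after their results could be seen, and the other tests before. Several genes outside the androgen-induced list changed course between ablation and independence. LINC00844 fell by 1.64 at ablation and stood 1.27 above the dependent stage at independence, both on the log2 scale. GRB10 went from a signal of 2036 to 6947 at ablation and to 1829 at independence, where it did not differ from dependence (log2 fold change -0.16, adjusted p = 0.462). TAFA2 rose by 1.09 at ablation and at independence lay below dependence, with a log2 fold change of -1.24. ACKR3, from the androgen-repressed list, rose by 0.76 at ablation (adjusted p = 0.0357) and had -1.66 at independence against dependence. With the mean of its probe sets ACKR3 at independence had -1.29 against dependence and -1.19 against ablation, which leaves no rise at ablation.

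Mitosis genes were lower at ablation, with a median log2 fold change of -1.68. The scaling of each array is argued against, since the higher of the medians under quantile normalization and median centring was -1.746. A lower share of LNCaP cells is argued against as the whole cause, since 1 of 14 luminal markers, MSMB, lay at or below the mitosis median and ACP3 rose. Time in the fiber rather than androgen withdrawal cannot be told apart from castration, since 0 later arrays came without it. Slower division after androgen withdrawal may explain the fall, and stays a hypothesis.

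Returned genes numbered 58. Of 100 simulated draws in which independence equalled ablation 0 gave as many. These draws held no change between ablation and independence, and gave at most 1 returned gene. They argue only against independence equal to ablation, for noise independent between genes. In the data 380 genes passed between ablation and independence. How many of the 58 came from noise in the shared ablation arrays cannot be told from such draws. Deviations of an array that many genes share were not simulated, and chance from them stays open. Among genes lowered at ablation, 4 of 19 androgen-induced genes returned, 21.1%, against 36 of 758 others, 4.7% (Fisher's exact test, two-sided, p = 0.0133, odds ratio 5.32, 95% interval 1.22 to 17.9). With mouse as a block 1 of 16, TRPM8, returned against 6 of 474 others (Fisher's exact test, two-sided, p = 0.209, odds ratio 5.16, 95% interval 0.106 to 47). Whether return was more frequent among androgen-induced genes stays open, as does time in the fiber, since too few returned genes are left in the paired fit. The calls of all 4 also ended on leaving out single arrays, and GNMT was still below dependence.

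RLN2, RLN1 and CD274, which lie in 1 run of genes with PLGRKT between RLN1 and CD274, were higher at independence. A gain of the whole chromosome region is argued against, since the nearest 20 measured genes had a median log2 fold change of 0.183, with 4 higher and 0 lower. Adjacent genes changed together across the genome, with a mean product of standardised log2 fold changes of 0.0893. The highest of 1000 shuffles of gene order gave 0.0318. Shared local regulation may contribute, but the product cannot tell that from a short gain. The genes of this run entered the product too. A short gain from JAK2 (1.03, adjusted p = 0.00225) through PLGRKT (1.51) to CD274 stays open, with JAK2 and PLGRKT chosen after their values were seen. Probe sets shared between the relaxin paralogs RLN1 and RLN2 were not tested and would leave CD274 unexplained.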
